A study of Mus musculus with 6 samples.

How the data were processed

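Hippocampi of 6 APP/PS1 mice, a strain that carries amyloid transgenes, were profiled by Drop-Seq, which captures single cells with barcoded beads in droplets and counts transcripts from their 3' ends by unique molecular identifier (UMI). Per the labels, 3 mice had received an antisense oligonucleotide (ASO) and 3 had received phosphate buffered saline (PBS), and all were 10 weeks old. The study's title names reduction of IDOL, a ubiquitin ligase encoded by Mylip, so Mylip was taken as the targeted gene. The control was saline and not a control oligonucleotide, so an effect of oligonucleotides in general and an effect of the target are not separated by this design. Replicate numbers follow the order of the samples, and the labels do not pair mice.

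The authors deposited a table of counts of UMIs per gene and cell, with no normalization. Per the submitters' processing notes, bcl2fastq and STAR 2.5.0c were used with builds mm10 and GRCm38, and the counting program and gene annotation are not given in the sources used here. The table held 28324 genes, of which 24078 had at least 1 count, in 12823 cells. Every value was a whole number. Each column name carried the mouse and a cell class given by the authors. The cells in the table had at least 501 detected genes, 569 to 1999 UMIs and at most 15.0% of UMIs from mitochondrially encoded genes, so the planned limits of 200 genes and 15% removed no cell.

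Doublets were called per mouse with Scrublet as implemented in scanpy 1.11.5, and the 220 called cells (1.72%) were removed, which left 12603 cells. The 17 classes deposited by the authors were used as cell types in place of the clusters that had been planned before the data were examined, since they came with the table. Clusters computed here (Leiden algorithm, 2000 variable genes, 30 principal components, 15 neighbours, resolutions 0.5, 1.0 and 2.0) and a class per cell from fixed marker genes served as alternatives, and gave 94.8%, 94.7%, 94.5% and 86.6% of cells the deposited class.

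Raw counts were summed per mouse over all cells and over the cells of each class, since the mouse and not the cell is the replicate. A class was tested where every mouse had at least 20 cells of it. ASO and PBS mice were compared with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, glmQLFit and glmQLFTest with their defaults), two-sided, with Benjamini-Hochberg adjustment over the genes tested in that class and a threshold of 0.05. Normalised levels are CPM as edgeR defines it (counts scaled to one common library size) over the tested genes after TMM scaling, and levels of Mylip are CPM of all UMIs. A fit with robust estimation had been run as a first look before the planned default fit, and is kept as an added alternative. Means are given with the SD over 3 mice, and log2 fold changes (ASO minus PBS) with their standard error (SE).

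Gene lists fixed before the data were examined were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, in each class where at least 3 members were tested, with adjustment over the 189 tests. An estimated correlation, fry, and the lists without shared genes were alternatives. Marker lists of cell types were tested the same way as a check of sample makeup. Shares of cells per class were compared by an exact two-sided permutation test over 20 assignments, for which 0.1 is the smallest p. Whether an ASO effect differed between classes was tested with an edgeR interaction model with mouse as a block, on the effect in one class minus the mean effect in the other tested classes. After a first run it was restricted to 7352 genes with a count in every class and group, because the contrast has no bound elsewhere, and a comparison with the summed counts of the other classes was added.

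Named genes followed a rule fixed in advance: Mylip in every class, Vldlr, Lrp8 and related receptors in the whole library (not all of them reported here), up to 12 higher and 12 lower called genes per class, the genes nearest to the threshold where fewer than 4 passed, up to 4 members of each list past its threshold and up to 2 of the others. Genes named outside this rule are marked as chosen after their values were seen. Other alternatives were DESeq2 size factors, no filter on low counts, DESeq2 1.42.0, limma voom, a mitochondrial limit of 10%, doublets kept, totals thinned to equality, and each mouse left out in turn. Added after the data were seen were a term for 3 sets of 2 mice that differed in the ratio of mt-Rnr2 to mt-Cytb, and fits without cells that held a UMI of a macrophage or an endothelial marker. Each of the 3 sets held the PBS and the ASO mouse of the same replicate number. The main test ignored this pairing, which was seen in the data. Deviations of log2 CPM from the group mean correlated at 0.206, 0.178 and 0.0879 within sets and at -0.176 to -0.00935 across them. Because deviations were taken from group means, positive values within sets push those across sets below 0, so the negative values add no separate support for the sets.

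Total UMIs per mouse ranged from 2005768 to 3134558. Beside a share or level of 0, the value that 3 counts would make is given as a floor. It is smaller than an exact upper limit. Intervals are 95% exact Poisson or binomial intervals that cover counting error only. The procedure was tested on simulated counts with the real means and library sizes, in which 200 genes were changed. All genes of a fit were drawn with 1 common dispersion and without technical sets, so recovery from real counts may be lower. The procedure called up to 7 unchanged genes in a fit (endothelial cells). Of 100 genes changed 2-fold, it recovered 70 in the whole library, 56 in oligodendrocytes, 45 in microglia, 29 in mural cells, 30 in oligodendrocyte precursors and 32 in subiculum neurons, and of 100 genes changed 1.5-fold, 29, 12, 11, 4, 8 and 7. No 2 mice of a group held counts that differed by less than sampling noise (chi-square per degree of freedom 3.47 to 6.59). Gene positions are from a GENCODE annotation of GRCm38.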

Results

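Single-cell RNA profiles were collected from the hippocampus of 3 ASO-treated and 3 PBS-treated APP/PS1 mice. After removal of doublets, the PBS mice contributed 1821, 2013 and 2110 cells with 2127919, 2256386 and 2433090 UMIs. The ASO mice contributed 2809, 2099 and 1751 cells with 3134558, 2352782 and 2005768 UMIs. Median UMIs per cell lay between 1027 and 1096 in the 6 mice. The largest classes were oligodendrocytes (2999 cells), astrocytes (1877), microglia and macrophages (1849), endothelial cells (1808), dentate neurons (1122) and oligodendrocyte precursors (944).

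The first comparison asks how far Mylip RNA, which encodes the ubiquitin ligase IDOL, was lowered and in which cells. Mylip lies on chromosome 13 at 45389742 to 45412022 of GRCm38, on the plus strand. In all cells together its level was 68.3 ± 7.47 CPM in PBS mice and 34.3 ± 4.39 CPM in ASO mice (SD, n = 3 each), and every ASO mouse lay below every PBS mouse. The UMI counts were 128, 158 and 182 in PBS mice and 122, 71 and 68 in ASO mice. The log2 fold change was -0.98 (SE 0.157), and the edgeR adjusted p over all genes was 0.0547, which misses the threshold. That adjustment spans the 14001 genes tested, although Mylip was named as the target before the data were examined.

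Microglia and macrophages held 74.3% of all Mylip UMIs. There Mylip fell from 373 ± 18.2 to 181 ± 15.7 CPM (SD, n = 3 each), a log2 fold change of -1.04 (SE 0.178, edgeR adjusted p = 0.00475), and was lower in each of the 3 ASO mice. Without ASO replicate 1 the log2 fold change of Mylip was -0.995 with an edgeR adjusted p of 0.238, and over all 20 alternatives the adjusted p ran from 0.000786 to 0.238. In endothelial cells, the class with the next largest number of Mylip UMIs, 34 UMIs in PBS mice stood against 33 in ASO mice, with a log2 fold change of -0.09 (SE 0.380, edgeR adjusted p = 0.998). Dentate neurons held 15 UMIs in PBS mice and 1 in ASO mice, and mural cells held 15 in each group. No Mylip UMI was seen in choroid plexus, ependymal or Cajal-Retzius cells, where 3 UMIs over all mice would make 51.1, 12.8 and 9.92 CPM. The effect on Mylip in microglia minus that in all other classes summed was -0.51 (SE 0.308). The edgeR p was 0.0986 unadjusted and 0.981 adjusted over all genes, so a difference between microglia and other cells was not shown.

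**Figure D1:**
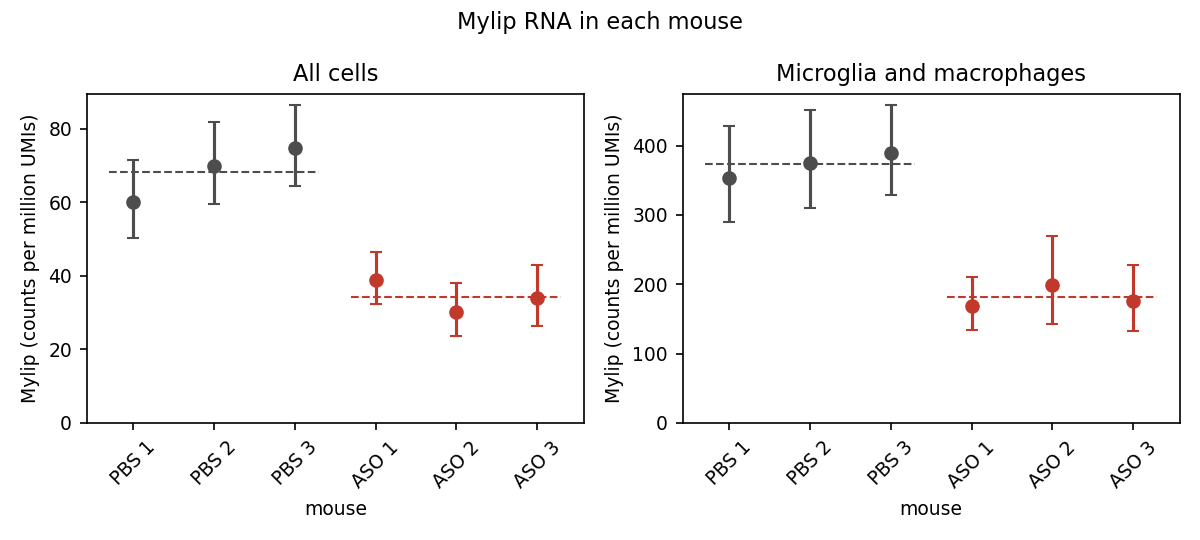
Mylip level in CPM of all UMIs (vertical axis) in each of the 6 mice (horizontal axis), in all cells and in microglia and macrophages; bars are 95% exact Poisson intervals and dashed lines are group means. The means are 68.3 and 34.3 CPM in all cells and 373 and 181 CPM in microglia and macrophages.

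IDOL marks lipoprotein receptors for degradation, so RNA of lipoprotein receptors and of sterol pathways was compared next. In the whole library Vldlr, a receptor for lipoproteins rich in triglyceride, had a log2 fold change of 0.05 (SE 0.145) and Lrp8, a reelin receptor, of -0.07 (SE 0.157), with edgeR adjusted p values of 0.999. The sign of Vldlr changed with a mitochondrial limit of 10% (-0.0139), and that of both with PBS replicate 2 left out (-0.0255 and 0.0517). Of 17 targets of the sterol-sensing LXR receptors, 14 were higher in the whole library, with no member past the threshold (camera adjusted p = 0.066, and 0.941 with an estimated correlation). Of 22 genes of cholesterol synthesis, 12 were higher and 10 lower (camera adjusted p = 0.947). Of 21 genes of amyloid precursor processing, 16 were higher and 5 lower (camera adjusted p = 0.273). These comparisons concern RNA, and receptor protein was not analysed here.

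Microglia and macrophages of ASO mice had more Lyz2, which encodes a lysozyme of myeloid cells, at 2419 ± 332 against 1305 ± 383 normalised CPM (SD, n = 3 each). The log2 fold change of Lyz2 was 0.90 (SE 0.176, edgeR adjusted p = 0.0262). Mylip and Lyz2 were the only genes past the threshold among the 5467 tested in this class. Without PBS replicates 1, 2 and 3 the counts of called genes were 2, 5 and 9, and without ASO replicates 1, 2 and 3 they were 0, 7 and 2. Lyz2 has a near-identical copy, Lyz1, and counts of the pair are uncertain. Lyz2 missed the threshold without PBS replicate 1 (adjusted p = 0.0686), without ASO replicate 1 (0.459), without ASO replicate 3 (0.0717), with a term for 3 technical sets (0.0741) and without cells that held a macrophage marker UMI (0.225).

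Of 28 genes of the disease-associated microglia list, a state described around amyloid plaques, 27 were higher in the microglia and macrophages of ASO mice. The median log2 fold change was 0.32 (camera adjusted p = 5.87e-07), and with an estimated correlation the adjusted p was 0.941. Lyz2 passed over all genes, and 4 members passed adjusted over the list alone: Lyz2, Apoe at 0.81 (SE 0.185), Spp1 at 1.64 (SE 0.428) and Cst7 at 0.46 (SE 0.160), in log2 fold change. Within the technical set of the mice numbered 2, the log2 difference was only 0.233 for Lyz2 and 0.0702 for Apoe. In the other sets it was 1.11 and 1.41 for Lyz2 and 1.14 and 1.22 for Apoe. Of 18 homeostatic microglia genes, 14 were lower (camera adjusted p = 0.0737), among them Tmem119 at -0.44 (SE 0.161). Markers of perivascular macrophages were also higher in this class, 6 of 6, with a median log2 fold change of 0.48 (camera adjusted p = 0.00442, and 0.704 with an estimated correlation), and so were oligodendrocyte markers, 5 of 6 (camera adjusted p = 0.0204, and 0.704 with an estimated correlation). Cells with a UMI of a macrophage marker were 2.83% to 7.96% of the class in PBS mice and 7.46% to 10.1% in ASO mice.

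Other lists in microglia and macrophages passed with the preset correlation, and each had an adjusted p of 0.941 with an estimated correlation. Lysosomal genes were higher (24 of 30, camera adjusted p = 0.0231), as were interferon response genes (7 of 7, 0.00409), inflammatory and NF-kB genes (13 of 16, 0.0106), ribosomal protein genes (69 of 79, 0.00176) and nuclear genes of oxidative phosphorylation (56 of 72, 0.000596). Immediate early and dissociation stress genes, which also respond to tissue handling, were lower (19 of 21, 0.0106). Without genes named in more than 1 list, the adjusted p was 0.132 for lysosomal and 0.0586 for inflammatory genes. Over all classes, 20 of 189 list tests passed with the preset correlation and 0 with an estimated one.

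**Figure D2:**
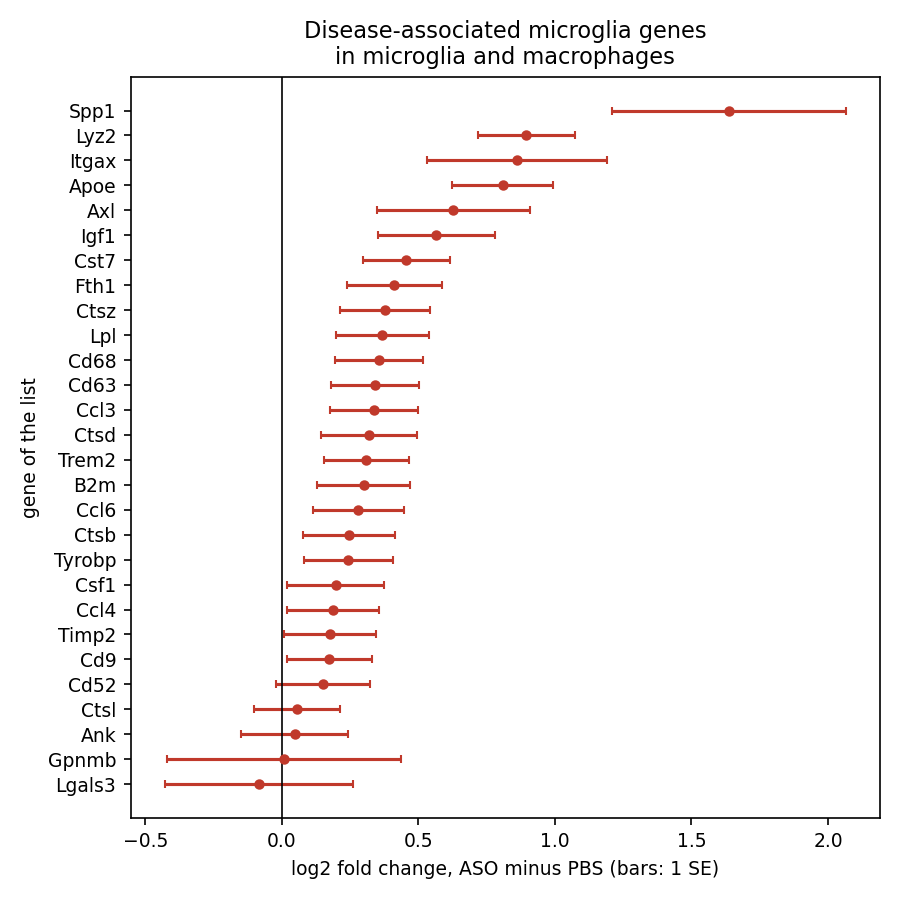
Log2 fold change, ASO minus PBS (horizontal axis), of each tested gene of the disease-associated microglia list (vertical axis) in microglia and macrophages; points are edgeR estimates and bars are 1 SE. Points lie above 0 for 27 of 28 genes.

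Oligodendrocytes had the most called genes, 10 higher and 6 lower in ASO mice among 7141 tested. Higher were Cntn1, a neural adhesion molecule, at 168 ± 10.2 against 39.0 ± 1.38 normalised CPM (SD, n = 3 each; log2 fold change 2.10, SE 0.214, edgeR adjusted p = 1.92e-06), and Marcks, a substrate of protein kinase C, at 75.5 ± 20.4 against 7.95 ± 3.40 normalised CPM (log2 fold change 3.22, SE 0.376, adjusted p = 1.45e-05). Ppp1r17, Syt4 and Mgst1 were close to 0 in PBS mice, so their fitted folds depend on few counts. Ppp1r17 was seen in 0% (3 cells would make 0.659%) to 0.466% of oligodendrocytes of PBS mice and in 2.89% to 3.71% of those of ASO mice. Neat1, Gria2, Kank1, Cela1 and Rnase4 had log2 fold changes between 0.77 and 1.80. Lower were Slco3a1 (-1.45), Ttll5 (-1.38), Arl4d (-1.17), the kinase gene Sgk1 (-1.08), Fbxw15 (-1.003) and Hipk2 (-0.84). For each of the 16 genes the ASO and PBS mice lay apart, as they did for 11.5% of all genes tested in this class, where chance gives 10%.

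Cntn1, Marcks, Ppp1r17, Slco3a1 and Ttll5 passed under all 19 alternatives, while Gria2 passed under 9. Syt4 had an adjusted p of 0.569 with a robust edgeR fit, and Sgk1 of 0.812 with DESeq2. Without PBS replicate 3, 6 of the 16 genes passed, and without ASO replicates 1, 2 and 3 the counts of called genes were 26, 30 and 25. Of the 9 genes other than Neat1 that were higher, at least 3 were seen together in 71 of 1664 oligodendrocytes of ASO mice and in 0 of 1335 of PBS mice, the group in which the genes were chosen to be lower, where 3 cells would make 0.659%, 0.665% and 0.699% in the 3 mice. In PBS and ASO mice the shares were 0.338% and 0.109% in endothelial cells, 2.95% and 3.32% in microglia and macrophages, 5.18% and 5.66% in astrocytes and 56.5% and 53.1% in oligodendrocyte precursors. Median depths were 1034 and 1039 UMIs in oligodendrocytes, 1040 and 1013 in endothelial cells, 977 and 997 in microglia and macrophages, 1118 and 1075 in astrocytes and 1101 and 1010 in precursors. Haemoglobin genes were high in the oligodendrocytes of ASO replicate 2 alone, with Hbb-bs at 744 CPM there and 62.4 to 85.8 CPM in the other mice. Of 3 haemoglobin genes, 3 were higher, 3 passed adjusted over the list alone and 0 over all genes (camera adjusted p = 0.113, and 0.941 with an estimated correlation). All 15 tested immediate early and dissociation stress genes were lower in oligodendrocytes (camera adjusted p = 0.000168, and 0.941 with an estimated correlation), and 15 of 16 myelin genes were lower (camera adjusted p = 0.0526).

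**Figure D3:**
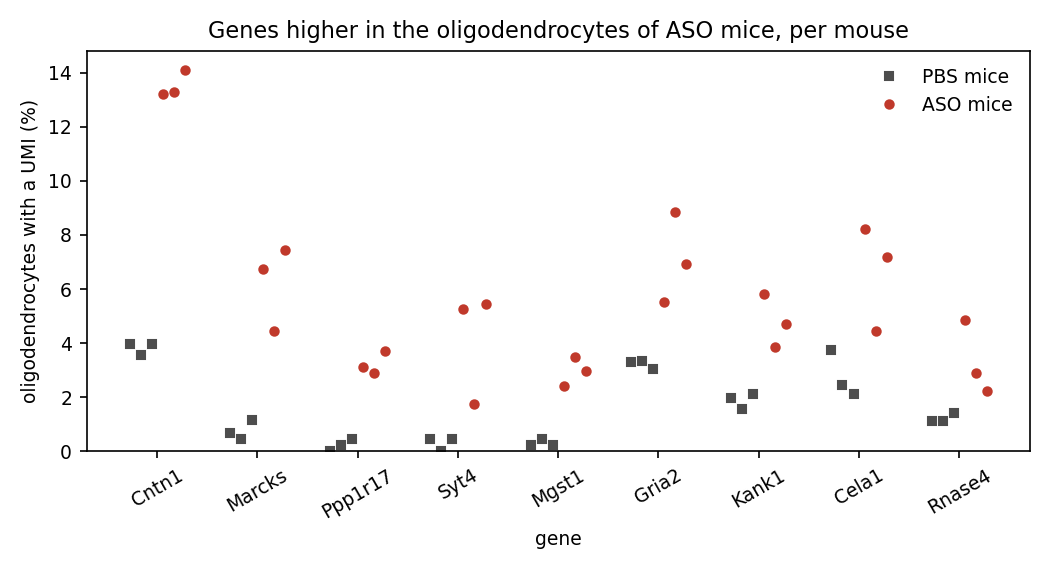
Percentage of oligodendrocytes with at least 1 UMI (vertical axis) of 9 genes called higher in ASO mice (horizontal axis); each point is a mouse. For Cntn1 the PBS mice lie between 3.55% and 3.96% and the ASO mice between 13.2% and 14.1%.

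In mural cells, Mt1, a metallothionein, was higher in ASO mice (log2 fold change 0.95, SE 0.205, edgeR adjusted p = 0.0203), and Slc39a10 (-2.33, SE 0.426), Eltd1 (-1.99, SE 0.392) and the drug efflux pump gene Abcb1a (-1.78, SE 0.367) were lower. Markers of endothelial cells were lower in this class, 6 of 6, with a median log2 fold change of -0.74 (camera adjusted p = 0.001, and 0.704 with an estimated correlation). With mural cells defined by Leiden clusters or by markers per cell, the log2 fold changes lay between -0.85 and -0.43 for Slc39a10, -0.94 and -0.49 for Eltd1 and -0.56 and -0.22 for Abcb1a, and none of the 3 genes passed (adjusted p 0.0733 to 0.978). Mt1 was at 0.456 (adjusted p = 0.914) without mural cells that held an endothelial marker UMI. edgeR had 134 genes at an unadjusted p under 0.05 in mural cells, where 77.9 would be expected by chance, and DESeq2 and limma voom called 0. Without PBS replicates 1, 2 and 3 the counts of called genes were 2, 1 and 0, and without ASO replicates 1, 2 and 3 they were 0, 22 and 0. In oligodendrocyte precursors, Frmd4a was lower (-1.43, SE 0.287, edgeR adjusted p = 0.0217) and Ptgds higher (2.35, SE 0.438, adjusted p = 0.0127), but without ASO replicate 1 the log2 fold change of Ptgds was 0.996 (adjusted p = 0.744) and Frmd4a had an adjusted p of 0.523. Without PBS replicate 1 the adjusted p was 0.0897 for Ptgds and 0.445 for Frmd4a. Ptgds also missed the threshold with precursors defined by Leiden clusters at each resolution. In subiculum neurons, Trpm3, a calcium-permeable channel (-1.67, SE 0.362, edgeR adjusted p = 0.0248), and Nlgn1, a synaptic adhesion molecule (-1.35, SE 0.308, adjusted p = 0.0272), were lower, and both missed the threshold without PBS replicate 3 (Trpm3 0.430, Nlgn1 0.129) or ASO replicate 2 (0.495 each). Nlgn1 also missed it without PBS replicate 1 (0.376) or ASO replicate 3 (0.104).

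In the whole library Ppp1r17 was the only called gene (12.4 ± 3.35 against 1.05 ± 0.314 normalised CPM; log2 fold change 3.50, SE 0.435, edgeR adjusted p = 0.00391), and it missed the threshold without PBS replicate 2 (0.0752) or PBS replicate 3 (0.0832). Without ASO replicate 2, 8 genes passed in the whole library. edgeR, DESeq2 and limma voom each called 0 genes in astrocytes, endothelial cells and CA1, Cajal-Retzius and dentate neurons. There 218, 253, 45, 46 and 168 genes had an unadjusted edgeR p under 0.05. By chance 314, 311, 47.15, 51.85 and 253 would be expected, which is more in each class.

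The share of cells in each class was compared next. No class passed the exact permutation test, in which 0.1 is the smallest p that 3 against 3 mice can give and the lowest adjusted p was 0.34. Dentate neurons made up 10.4 ± 1.97% of cells in PBS mice and 7.59 ± 0.858% in ASO mice, and interneurons 0.656 ± 0.00920% and 0.986 ± 0.0678% (SD, n = 3 each). Without PBS replicate 3 the difference for dentate neurons went from -2.79 to -1.65 percentage points, and with a class per cell from markers it was -1.09. Microglia and macrophages made up 15.3 ± 1.24% and 14.0 ± 3.92%. ASO replicate 2 had 9.58%, and without it the difference went from -1.31 to 0.918 percentage points.

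Whether the ASO effect in microglia differed from that in other classes was tested gene by gene. edgeR called 0 of 7352 genes against the mean of the other classes, with 4.38% of them at an unadjusted p under 0.05, and 2 genes against the other classes summed. For Apoe the difference was 0.70 (SE 0.191, edgeR adjusted p = 0.881).

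Signs of sample makeup were checked in the same counts. Xist had 0 to 2 UMIs per mouse and the Y-linked gene Ddx3y 125 to 163 CPM, as in male mice. RNA of Ttr, a choroid plexus transcript, was 51.1 CPM in the microglia of PBS replicate 3 and 2317 to 7136 CPM in those of the other mice. This was not particular to microglia. In the same mouse Ttr was 56.4 CPM in oligodendrocytes and 38.25 CPM in endothelial cells, against 2038 to 6158 and 1867 to 6485 CPM in the others. Choroid plexus cells held 258200 to 345200 CPM. In the Cajal-Retzius class Ttr was 34500, 12080 and 21210 CPM in PBS mice and 22550, 40290 and 98400 CPM in ASO mice.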

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

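The tests of explanations and the counts of splits for called genes in this part were chosen after the results they concern had been seen, while the counts of splits for the list tests and for the difference between microglia and other classes were planned before. The differences named here are between the ASO effect in one class and the mean effect in the other tested classes, by an interaction test that was planned.

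Lyz2 and 27 of 28 disease-associated microglia genes were higher in the microglia and macrophages of ASO mice, and macrophage markers were higher there too, but with an estimated correlation the adjusted p was 0.941 for the list and 0.704 for the markers. Without the cells that held a macrophage marker UMI, 26 genes of the list had a value, and Spp1 had none. Their median log2 fold change went from 0.315 to 0.302 with 25 of 26 genes higher. This argues against detected macrophages as the whole source for these 26 genes, and says nothing on Spp1. Apoe was at 0.667 (SE 0.173, edgeR adjusted p = 0.225) in that fit. Lyz2 itself went from 0.90 (SE 0.176) to 0.644 (SE 0.167), and its adjusted p to 0.225, so a contribution of macrophages to Lyz2 cannot be told apart from a change within microglia; macrophages with no marker UMI also remain in both. For the 25 list members that gained CPM in microglia, free RNA was argued against as the source. Their gain outside microglia was 0.0153 of the gain inside (median, upper quartile 0.0345). An effect of Mylip reduction and one of oligonucleotides in general both stay open, untested, because the control was saline.

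In oligodendrocytes the effect on Cntn1 (2.17), Syt4 (4.66) and Marcks (3.24) differed from that in the other classes. Of 9 called genes, at least 3 were seen together in 71 of 1664 oligodendrocytes of ASO mice, against at most 39 in 1000 shuffles, so detection in separate cells is argued against; in PBS and ASO mice endothelial cells had 0.338% and 0.109% such cells, microglia and macrophages 2.95% and 3.32%, astrocytes 5.18% and 5.66%, CA1 neurons 13.8% and 20.7%, dentate neurons 18.5% and 16.0%, subiculum neurons 25.3% and 23.2% and precursors 56.5% and 53.1%. RNA of excitatory neurons is argued against, since excitatory neuron markers gained 0.0231% of their neuronal level (SE 0.175) where 1.86% was needed. RNA of interneurons and of Cajal-Retzius neurons was not tested. In PBS and ASO mice, cells with at least 3 of the genes were 5.13% and 12.1% of interneurons (2 of 39 and 8 of 66). They were 10.2% and 5.88% of Cajal-Retzius neurons. For precursor RNA, markers gained 0.255% of their precursor level (SE 1.05): Cntn1, Kank1, Syt4, Mgst1, Cela1 and Rnase4 would need at least 10.0%, and Ppp1r17, with 0 UMIs in the precursors of ASO mice, 823% of the level that 3 UMIs would make there, which argues against it for these, but Marcks and Gria2 would need 3.49%, so for these it cannot be told apart from a change in oligodendrocytes. A distinct oligodendrocyte state in ASO mice is a hypothesis, found and tested on the same data.

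In mural cells the effect on Slc39a10 (-2.15) differed from that in the other classes, and Slc39a10, Eltd1 and Abcb1a were all lower. A fit without cells that held an endothelial marker UMI was void for this question, because none of the 3 genes was then tested; such cells were 45.5% to 63.3% of mural cells in PBS mice and 33.6% to 39.7% in ASO mice. The test used in its place was the other genes at least 5 times as high in endothelial as in mural cells: 24 of 24 were lower, with a median log2 fold change of -0.865, against a mean of -2.03 for the 3 genes. Of the UMIs of these genes in mural cells, 61 of Slc39a10, 74 of Eltd1 and 103 of Abcb1a were in cells with an endothelial marker UMI, and 9, 0 and 3 in the others. Less endothelial RNA in the mural cells of ASO mice therefore may account for some or all of the change. It cannot be told apart from a change in mural cells. The median fell short of the bound set for endothelial RNA as the whole source. That bound was drawn from 3 called genes after their values were seen, so the shortfall does not decide the question. For Eltd1 and Abcb1a hardly any UMIs lay outside the cells with an endothelial marker UMI.

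Other effects also differed between one class and the mean of the others. In astrocytes the differences were -1.68 for Igfbp5 and -1.87 for Gria4, which was high in PBS replicate 3 alone. Against the other classes summed, Gria4 was called in astrocytes (edgeR adjusted p = 0.000232) and Igfbp5 was not. In CA1 neurons Hbb-bs, a haemoglobin gene, differed by 5.27. Against the other classes summed, Hbb-bs differed by 4.31 there, 2.85 in dentate neurons, 1.61 in oligodendrocytes and -1.40 in endothelial cells. Its difference was therefore not particular to CA1 neurons. In subiculum neurons the differences were -1.82 for Trpm3, -1.19 for Nlgn1 and -1.29 for Lingo2. Against the other classes summed, however, edgeR called 0 genes there (Trpm3 adjusted p = 0.319, Nlgn1 0.566). In that comparison 447 of 12432 genes (3.6%) had an unadjusted p under 0.05, fewer than chance would give. In oligodendrocytes Phlpp1 differed by -0.96, and in oligodendrocyte precursors Frmd4a by -1.43. Igfbp5, Gria4, Hbb-bs and Phlpp1 were named because of this test, after their values were seen.

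The 6 mice can be divided into 3 and 3 in 10 ways, too few for a share under 0.05. These splits took no account of the technical sets. In oligodendrocytes 1 of the 10 splits gave as many called genes (16, highest other 0), in mural cells 1 (4, highest other 2) and in subiculum neurons 1 (2, highest other 1). In the whole library 2 splits did (1, highest other 1), in oligodendrocyte precursors 2 (2, highest other 3) and in microglia and macrophages 3 (2, highest other 6). Astrocytes, endothelial cells and CA1, Cajal-Retzius and dentate neurons had 0 called genes, which all 10 splits equal, and their highest other counts were 2, 4, 1, 1 and 2. The difference in effect between microglia and other classes gave 0 in all 10. The list tests gave 20 calls, which 7 of the 10 splits equal or exceed, with a highest other of 41.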

How the results depend on the processing

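The term for 3 technical sets, the robust fit, Leiden clusters at resolution 1.0, the fits without marker-bearing cells and the comparison with the other classes summed were chosen after the data were seen, as were, for Mylip in the whole library alone, no filter, limma voom, the mitochondrial limit of 10% and doublets kept. The other alternatives were chosen before. Of 228 results for named genes, 27 were called, and 24 of 4081 values under alternatives changed sign, none of them of a called gene. With DESeq2 size factors all 27 calls stood, with limma voom 16, with DESeq2 11, and in oligodendrocytes Cntn1, Marcks, Ppp1r17, Slco3a1 and Ttll5 stood under all 19 alternatives. The limit of 500 genes removed 0 cells and gave no value of its own, and not every class could be formed from clusters. Except where fewer genes or mice were used, the cause of a change was not tested.

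Mylip in the whole library kept its direction and passed with no filter on low counts (-0.973), DESeq2 (-0.989), doublets kept (-0.995) and the robust fit (-0.983). All barcodes deposited were the same cells as with doublets kept, since the limits removed no cell, and gave the same fit. Counts of called genes changed by over 1.5 times as follows. With no filter they were 29 in the whole library, 2 in astrocytes, 9 in microglia and macrophages, 4 in CA1, 1 in Cajal-Retzius, 4 in dentate and 0 in subiculum neurons, 41 in oligodendrocytes and 5 in precursors. With DESeq2 they were 4 in the whole library, 8 in oligodendrocytes and 0 in mural cells, subiculum neurons and precursors. With limma voom they were 0 in mural cells, 1 in subiculum neurons and 0 in precursors. With doublets kept they were 2 in the whole library, which is the same fit as with all barcodes, and 2 in mural cells. With a mitochondrial limit of 10% the count was 1 in Cajal-Retzius neurons. With thinned totals they were 0 in mural cells, 3 in Cajal-Retzius and 0 in subiculum neurons and 1 in precursors. With Leiden clusters they were 0 in mural cells and 1 in dentate neurons at each resolution. In precursors they were 5, 5 and 0 at 0.5, 1.0 and 2.0, with 1 of each 5 also called in the main fit. With a class per cell from markers they were 9 in mural cells (1 of them also called in the main fit), 3 in Cajal-Retzius neurons and 1 in precursors. With the technical set term they were 2 in the whole library, 1 in microglia and macrophages, 4 in dentate and 6 in subiculum neurons, 31 in oligodendrocytes and 5 in precursors. With the robust fit they were 3 in the whole library, 4 in microglia and macrophages, 7 in mural cells, 1 in Cajal-Retzius neurons and 1 in precursors. Without cells that held an endothelial marker UMI, 1 gene was called in mural cells, and it was not called in the main fit. List tests gave 0 calls with an estimated correlation, 0 with fry, 14 of 173 without genes named in more than 1 list and 26 of 189 with the technical set term, against 20 of 189. Against the mean of the other classes, the ASO effect differed for 2 genes in astrocytes, 1 in mural cells, 1 in CA1 and 3 in subiculum neurons, 4 in oligodendrocytes and 1 in precursors, and for 0 in endothelial cells, Cajal-Retzius and dentate neurons. Against the others summed, it differed for 2 genes in microglia and macrophages, 3 in astrocytes, 5 in endothelial and 5 in mural cells, 4 in CA1, 1 in Cajal-Retzius, 4 in dentate and 0 in subiculum neurons, 25 in oligodendrocytes and 4 in precursors.

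When each mouse was left out in turn, Mylip in the whole library ranged from -1.09 to -0.895. Counts of called genes ranged from 0 to 8 in the whole library, 0 to 1 in astrocytes and in endothelial cells, 0 to 9 in microglia and macrophages, 0 to 22 in mural cells, 0 to 4 in Cajal-Retzius, 0 to 2 in dentate and 0 to 3 in subiculum neurons, 6 to 30 in oligodendrocytes and 0 to 5 in precursors. They stayed at 0 in CA1 neurons and for the difference between microglia and other classes, and for shares the design allowed only 0.

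The log2 fold changes that changed sign were those of Vldlr in the whole library with a mitochondrial limit of 10% (-0.0139), Wfdc17 in microglia without macrophage marker cells (-0.00587), Apoe in mural cells with thinned totals (-0.0395) and a class per cell (-0.0585), and Fasn in dentate neurons with thinned totals (-0.223) and the technical set term (-0.0357). In Cajal-Retzius neurons they were Apoe with each Leiden resolution (-0.0944) and, with a class per cell, Apoe (-0.283), Ctsl (-0.233) and Aplp1 (0.694). With mice left out, values ranged from -0.0255 to 0.154 for Vldlr, -0.163 to 0.0517 for Lrp8 and -0.392 to 0.0012 for Lrp12 in the whole library, -0.0867 to 0.619 for Fasn and -0.525 to 0.0255 for Scd1 in astrocytes, -0.203 to 0.00536 for Mylip in endothelial cells, -0.081 to 0.611 for Apoe in mural cells, -0.127 to 0.942 for Cd63 in Cajal-Retzius neurons, -0.398 to 0.242 for Fasn in dentate neurons and -0.0126 to 1.03 for Abca1 in precursors. Depth limited the smaller classes, where 1558 genes could be tested in mural cells, 943 in CA1, 1037 in Cajal-Retzius and 1062 in subiculum neurons.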

Other observations

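The test of gene length below was chosen after the result was seen, and the test of committed precursors was written before.

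In ASO mice, the oligodendrocytes with at least 3 of the 9 genes were compared with those with none. The other transcripts given here were chosen after their values were seen. UMIs were pooled over the mice, so no spread between mice is given. Ranked genes had at least 15 UMIs in the cells with at least 3 of the genes, which favours high ratios. Cdkn1a, an inhibitor of the cell cycle, was 7.34 times as high (32 against 55 UMIs) and Gdf15 21.0 times (15 against 9). Nupr1 was 11.6 times as high (22 against 24), Vim 12.6 times (17 against 17) and Serpina3n 3.87 times (23 against 75). The ratio was 40.4 for Tagln2 (16 against 5) and 20.4 for Fam46a (34 against 21). With so few UMIs these ratios are imprecise. Ptgds was 3.22 times as high, while the ratio was 0.799 for Mbp, 0.534 for Mog and 0.351 for Apod. Such cells were 4.45%, 3.28% and 5.20% of oligodendrocytes in the 3 ASO mice, and 0 of 455, 451 and 429 in the PBS mice, where the genes were chosen to be lower and 3 cells would make 0.659%, 0.665% and 0.699%. Their median depth was 1273 UMIs against 1004 in cells with none of the genes.

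In the whole library, RNA of the Cajal-Retzius markers was lower in ASO mice, 5 of 5, with a median log2 fold change of -0.57 (camera adjusted p = 0.0014, and 0.704 with an estimated correlation). Ependymal markers were higher, 8 of 8, with a median of 0.55 (camera adjusted p = 0.00442), as were choroid plexus markers, 7 of 7, with a median of 0.48 (0.00215), and perivascular macrophage markers, 6 of 7, with a median of 0.33 (0.0204), each with an adjusted p of 0.704 with an estimated correlation. Lists that passed there with the preset correlation, each with an adjusted p of 0.941 with an estimated one, were homeostatic microglia genes (16 of 18 lower, 0.000395), disease-associated microglia genes (25 of 28 higher, 0.00585), interferon response genes (20 of 22 higher, 0.00351) and choroid plexus genes (8 of 9 higher, 0.00644). The shares of these cells moved the same way as their markers. Cajal-Retzius cells made up 2.82% of cells in PBS mice and 2.01% in ASO mice, with every ASO mouse below every PBS mouse. Ependymal cells made up 1.29% and 1.70% and choroid plexus cells 0.259% and 0.359%, with overlap between the groups. Marker shifts in the whole library therefore cannot be told apart from shifts in cell numbers. Microglia and macrophages made up 9.58% of cells in ASO replicate 2 and 14.4% to 17.0% in the other 5 mice, and within that class the homeostatic list did not pass (0.0737). Ttr, the most abundant of the choroid plexus genes, stood at 1060 CPM in PBS replicate 3 and at 4067 to 9219 CPM in the other 5 mice. Genes of oxidative phosphorylation were higher in 70 of 90 (0.0336, and 0.957 with an estimated correlation).

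Each of the gene lists that follow had an adjusted p of 0.941 with an estimated correlation. In mural cells 18 of 19 immediate early and dissociation stress genes, which also respond to tissue handling, were higher (camera adjusted p = 0.000326, and 0.941 with an estimated correlation), among them Egr1 with a log2 fold change of 0.76 (SE 0.198). Barrier genes, which are genes of endothelial cells, were lower there, 5 of 5 (8.69e-05, and 0.941). Endothelial markers moved with them, 6 of 6 lower with a median of -0.74 (0.001, and 0.704), as did 24 of 24 other genes at least 5 times as high in endothelial as in mural cells. In the Cajal-Retzius class, where Ttr was also highest in ASO replicates 2 and 3 (40290 and 98400 CPM), 8 of 8 disease-associated microglia genes (0.00337, and 0.941 with an estimated correlation) and 9 of 9 lysosomal genes (0.0135, 0.941 with an estimated correlation, and 0.224 without genes named in more than 1 list) were higher. With the class formed from Leiden clusters, Apoe was at -0.0944 there, and with a class per cell Apoe was at -0.283 and Ctsl at -0.233. In dentate neurons 3 of 3 myelin genes were higher (0.0163). So were 3 of 3 tested oligodendrocyte markers there, an overlapping list (camera adjusted p = 0.0135, and 0.704 with an estimated correlation). In oligodendrocytes 3 of 3 antigen presentation genes were lower (0.00608), and in oligodendrocyte precursors 56 of 75 genes of oxidative phosphorylation were higher (0.046, and 0.0561 without genes named in more than 1 list). Of the members of these lists 1, Abcb1a in mural cells, passed over all genes.

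Trpm3 and Nlgn1, lower in subiculum neurons, span 856365 and 906246 bp, and of 182 genes there longer than 300000 bp, 130 were lower. The slope of log2 fold change on gene length was negative in every tested class. It was steepest in subiculum neurons (-0.117 per log10 bp) and least steep in endothelial cells (-0.0139). In the whole library the slope was -0.0545, and 413 of 555 genes longer than 300000 bp were lower. Such genes held 15.9% of subiculum UMIs in PBS replicate 1, 12.2% and 11.5% in the other PBS mice and 11.5%, 10.1% and 11.8% in ASO mice. After the trend of log2 fold change on gene length in this class was removed, the mean of Trpm3 and Nlgn1 went from -1.51 (SE 0.238) to -1.35. That test is void, because these 2 genes were picked as called genes and the trend was at most 0.246 in any gene, so its removal was bound to leave most of their mean. A length trend therefore cannot be told apart from other sources of the lower long genes.

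Frmd4a and, with a log2 fold change of -1.95 that did not pass (edgeR adjusted p = 0.139), Enpp6 were lower in oligodendrocyte precursors, and a hypothesis was that ASO mice had fewer precursors committed to differentiate. Of 14 tested genes of a committed precursor list, 10 were lower, with a median log2 fold change of -0.0917 and 0 past the threshold, so the test left open whether fewer committed cells may have been present.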
